A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

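The series holds 24 RNA sequencing libraries of Saccharomyces cerevisiae, 3 biological replicates of each of 4 genotypes in log phase and in the starvation phase at 48 h of culture. Per the labels, cells grew in synthetic medium with 2% glucose and added histidine, leucine, uracil and lysine, RNA was extracted with hot acid phenol and treated with DNase, and 1 µg of RNA entered poly(A) isolation and a directional library kit. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.39 and STAR 2.7.9a. The file analysed is a single table with a value for each feature and library. Its values are TPM as deposited by the authors, between 999639 and 999881 in total for each library. It holds no counts, so the depth of each library is unknown and no counting interval or floor is given. The annotation used for counting, the strand counted and the treatment of reads that match several genes are not stated.

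The table has 8009 lines, and 7121 of them name a gene. Empty lines, 4 in all, were not used. Symbols and introns were read from a reference annotation of release 64 of the yeast genome, matched by gene identifier for 6050 genes; a gap of at least 20 bp between coding parts counted as an intron. No position is given, because the build used for counting is not stated. The 92 spike-in RNAs, origins, repeat elements and ribosomal DNA spacers were left out of the tests. Genes with a TPM of at least 1 in at least 3 libraries were tested, which left 6449.

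Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, in 1 linear model with a mean for each of the 8 groups and an intensity trend in the empirical Bayes step. The model has 16 residual degrees of freedom, a prior of 3.41 and 19.4 in all. The comparisons were starvation against log phase in each genotype, each mutant against WT in each growth state, and the starvation response of each mutant against that of WT as an interaction term, 13 in all, adjusted by Benjamini-Hochberg over genes within each. A gene was called changed at an adjusted p under 0.05 and a difference of at least 1 on the log2 scale. The 6 comparisons between mutants were added after the data had been seen. Gene lists, 33 in all, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists and comparisons. The lists were written by hand, except that intron status in the lists that use it came from the annotation. Comparisons, lists, the naming rule and the main alternatives were chosen before the data were examined.

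The naming rule took NAM8, MUD1 and HSH49 in every group. It took for each comparison the 5 largest rises and 5 largest falls among changed coding genes with a mean of at least 10 TPM and, outside the interactions, no overlap between replicates; up to 2 changed members of each list; and the mating-type and auxotrophy markers as values. Genes named outside it are said to have been chosen after their values were seen.

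The alternatives tried were pseudocounts of 0.1 and 5, no filter and a minimum of 10 TPM, rescaling to mRNA, median centring, quantile normalization, trimmed mean scaling, a replicate block, a fit of only the groups compared, no intensity trend, library weights, intron status written by hand, and leaving out each library in turn. Library weights were estimated gene by gene, because the restricted likelihood method did not converge. Added after the data had been seen were scaling to the spike-in RNAs, which assumes equal amounts in each library although the amounts are unknown and the labels do not mention them, a test of all lines, fits within a growth state, and a fit without both hsh49::Q24P log libraries that held most LEU2 RNA.

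The pipeline was tested on simulated data with the layout and spread of hsh49::Q24P against WT, with 50 genes changed at each size among 6449. A change of 1 on the log2 scale passed the adjusted threshold in 82% of genes in log phase and 92% in starvation, and 50% and 52% of them were called changed because the call also needs a fitted difference of at least 1. A change of 1.5 was passed and called in 100% of genes in both, and 4 and 61 unchanged genes passed. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.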

Results

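RNA was measured by poly(A)-selected, strand-specific RNA sequencing in 24 libraries of budding yeast (Saccharomyces cerevisiae), 3 biological replicates in each of 8 groups. The groups cross 4 genotypes with 2 growth states, exponential growth (log phase) and the starvation phase at 48 h of culture (starvation). Beside WT, the genotypes were a point mutant of HSH49 (hsh49::Q24P) and deletions of NAM8 (nam8D) and MUD1 (mud1D). Hsh49 is a protein of the U2 snRNP, and Nam8 and Mud1 are proteins of the U1 snRNP, the particles that first recognise introns during splicing. The comparisons ask how the RNA of each mutant differs from that of WT in each growth state. Values are in TPM, a unit of transcript abundance scaled to a fixed total per library, given as mean ± SD with n = 3, and differences are on the log2 scale with their standard error (SE). The TPM of a library sum to between 999639 and 999881 and hold no record of the sequencing depth, so the depth behind each value is unknown.

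The mutated genes set the groups apart. NAM8 (YHR086W) stood at 29.0 ± 2.73 TPM in WT and at 0.188 ± 0.12 TPM in nam8D in log phase, and at 45.3 ± 1.67 and 0.119 ± 0.0804 TPM in starvation. MUD1 (YBR119W) stood at 38.1 ± 1.73 TPM in WT and at 2.91 ± 1.63 TPM in mud1D in log phase, and at 69.2 ± 4.5 and 3.58 ± 0.213 TPM in starvation. HSH49 (YOR319W) was present in the point mutant, at 45.5 ± 1.68 TPM against 38.8 ± 2.96 TPM in WT in log phase. Other markers also separated WT from the mutants. LEU2, an enzyme of leucine synthesis, stood at 5191 ± 698 TPM in WT in log phase, at 14.5 ± 14.5 TPM in nam8D, at 3.37 ± 1.38 TPM in mud1D, and at 465.5, 117.6 and 63.03 TPM in the 3 hsh49::Q24P libraries. URA3, an enzyme of uracil synthesis, stood at 4.96 ± 1.12 TPM in WT and was listed at 0 in every nam8D and mud1D library. In the hsh49::Q24P log libraries it stood at 0.4585, 0.075 and 0.03908 TPM. In starvation LEU2 stood at 4482 ± 463 TPM in WT and at 0.925 ± 0.152, 4.35 ± 1.41 and 4.59 ± 1.29 TPM in hsh49::Q24P, nam8D and mud1D, and URA3 was listed at 0 in all mutant libraries. All groups carried the markers of mating type a: in WT log phase the pheromone gene MFA1 stood at 2062 ± 129 TPM and its counterpart of the other mating type, MF(ALPHA)1, at 0.85 ± 0.131 TPM.

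Growth state separated the libraries first. The first principal component held 82.3% of the variance and divided log phase from starvation, and the second held 9% and divided WT from the mutants in starvation. Replicates of a group correlated across genes with r between 0.9845 and 0.997; genes are not independent replicates, so no test is attached. The median SD of a gene between replicates was largest in hsh49::Q24P starvation, at 0.19 on the log2 scale, against 0.0883 in WT starvation and 0.0754 in WT log phase.

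**Figure D1:**
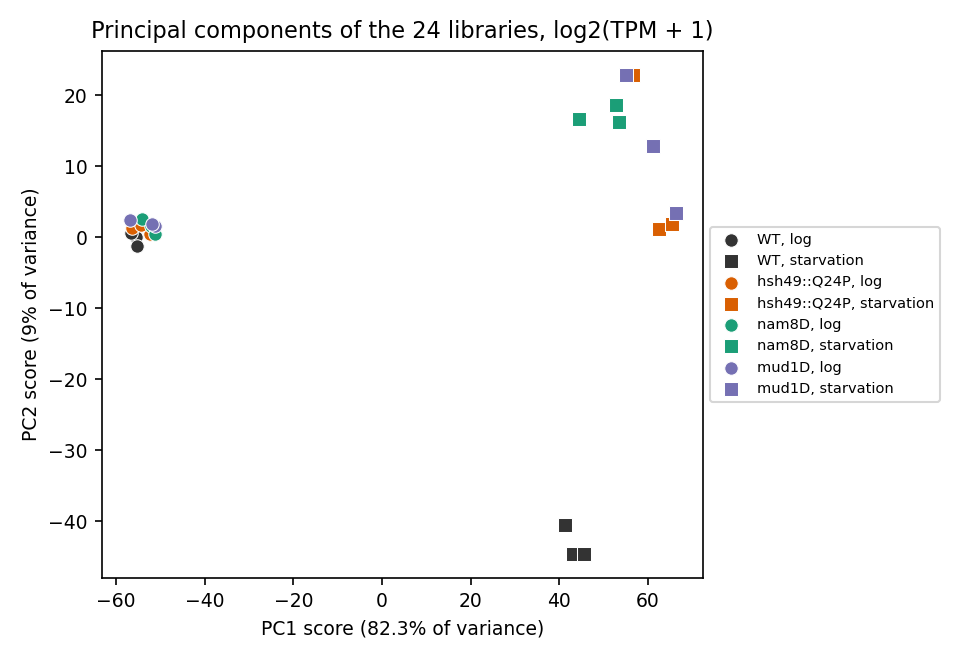
Scores of the 24 libraries on the first 2 principal components of log2(TPM + 1); each point is a library, circles are log phase, squares are starvation and colours are genotypes. The 3 WT starvation libraries lie between -44.6 and -40.5 on the second component, and the 9 mutant starvation libraries lie between 1.14 and 22.9.

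Starved WT cells turned from sugar use and growth to respiration and gluconeogenesis. Among 26 tested genes of gluconeogenesis and the glyoxylate cycle, 24 rose and 1 fell. The succinate-fumarate carrier SFC1 went from 0.457 ± 0.155 to 1596 ± 213 TPM and the malate synthase MLS1 from 1.22 ± 0.363 to 2088 ± 235 TPM. Of 37 nuclear genes of the respiratory chain 36 rose, as did 19 of 22 genes of the TCA cycle, 32 of 37 stress genes, 22 of 24 stationary-phase genes, 20 of 26 genes of fatty acid beta-oxidation and 30 of 38 autophagy genes. Examples are the external NADH dehydrogenase NDE2 (6.68 ± 0.434 on the log2 scale), the hydrophilin GRE1 (7.72 ± 0.275), the thiolase POT1 (5.56 ± 0.372) and the autophagy receptor ATG39 (4.18 ± 0.0927). The translation machinery went down: 74 of 89 ribosomal protein genes with an intron fell, 39 of 48 without an intron, 27 of 88 ribosome biogenesis genes and 8 of 35 translation factors, and in each list the other members stayed under the change called. RPL9A, which has a near-identical copy, fell from 2200 ± 19.7 to 280.8 ± 39.3 TPM. Of 20 glycolysis genes 14 fell and 2 rose, among them the enolase ENO2, from 11630 ± 206 to 508.9 ± 73.3 TPM; the split of reads between ENO2 and its near-identical copy ENO1 is uncertain.

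The largest single rises in WT starvation were those of DPA10, from 0.387 ± 0.377 to 7545 ± 840 TPM, SFC1, MLS1, the gluconeogenic phosphatase FBP1 (8.77 ± 0.59) and the acetate carrier ADY2 (8.72 ± 0.621). The largest falls were those of the cell wall enzyme UTR2, from 371.2 ± 13.1 to 5.48 ± 1.08 TPM, the glucose transporter HXT1, from 233.1 ± 22.2 to 3.84 ± 0.249 TPM, the transporter OPT2 (-5.22 ± 0.16), AIM20 (-4.60 ± 0.128) and ENO2. NAM8, MUD1 and HSH49 were higher in starvation by 0.63, 0.84 and 0.77 on the log2 scale, under a doubling, with limma adjusted p of 0.00178, 0.000124 and 1.15e-07. In limma, 1691 of 6449 genes rose and 581 fell, and 5214 passed the Benjamini-Hochberg adjusted threshold at any size. The median gene was 0.471 higher in starvation. With each library centred on its median the split became 845 up and 1038 down, so the share of rising genes rests on the scaling. Relative to the median gene the lists stood at 5.46 (gluconeogenesis), 1.89 (respiratory chain), 2.22 (TCA cycle), 1.88 (stress), 1.71 (stationary phase), 1.01 (beta-oxidation), 0.901 (autophagy), -1.77 (both ribosomal protein lists), -1.26 (ribosome biogenesis), -1.13 (translation factors) and -2.31 (glycolysis). Their limma camera tests gave adjusted p from 8.53e-34 to 0.000387, and adjusted p from 0.575 to 0.684 with an estimated correlation, so none of these list calls held there. Adjusted over the list alone, the counts of these lists were the same. For the proteasome, where 1 of 34 genes rose (RPN4, the activator of proteasome genes, 2.49 ± 0.0689), the list median was 0.349 higher but -0.122 relative to the median gene, while the camera test pointed up (adjusted p = 0.0212, and adjusted p = 0.614 with an estimated correlation). The list median turned negative with median centring, quantile and trimmed mean scaling.

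In starved hsh49::Q24P cells all 37 respiratory chain genes rose, 22 of 26 gluconeogenesis genes rose and 2 fell, and 60 of 88 ribosome biogenesis genes, 63 of 89 intron-containing and 38 of 48 intronless ribosomal protein genes fell. Ergosterol genes, whose products make the main sterol of the membrane, fell in 16 of 24 cases, and 17 of 35 histone and cell-cycle genes fell. The lactate carrier JEN1 rose most, from 2.60 ± 0.442 to 3943 ± 2070 TPM, followed by MLS1 (8.72 ± 0.427), ADY2 (8.58 ± 0.621), SFC1 (8.37 ± 0.596) and the stationary-phase gene SPG4 (8.20 ± 0.177). ENO2 (-6.54 ± 0.116), UTR2 (-6.53 ± 0.126), the cell wall gene SRL1 (-6.27 ± 0.147) and the daughter-cell gene DSE1 (-6.03 ± 0.125) fell most, beside LEU2 (-6.31 ± 0.572), whose log-phase RNA differed between the replicates. MUD1 rose by 1.07 ± 0.168, but stood at -0.02 with libraries scaled to the spike-in RNAs. The labels do not mention these RNAs and the amount added to each library is unknown, so values with spike-in scaling assume equal amounts per library. In limma 1836 genes rose and 910 fell (5257 passing at any size); centred on the library medians the split was 1253 and 1278. Relative to a median gene at 0.386, the respiratory chain stood at 2.45, gluconeogenesis at 4.59, ribosome biogenesis at -1.91, the ribosomal protein lists at -1.72 and -1.84, ergosterol at -1.68 and the histone and cell-cycle list at -1.26, with limma camera adjusted p from 5.3e-22 to 0.00176 and adjusted p from 0.575 to 0.711 with an estimated correlation.

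In starved nam8D cells 21 of 26 gluconeogenesis genes rose and 1 fell, all 37 respiratory chain genes rose, and 19 of 37 stress genes rose and 1 fell. Of the ribosomal protein genes, 38 of 89 with an intron and 24 of 48 without fell, with 1 rise in each list, and 27 of 88 ribosome biogenesis genes fell and 1 rose. Ergosterol genes fell in 14 of 24 cases. The largest rises were those of the alcohol dehydrogenase ADH7, from 2.54 ± 0.469 to 1867 ± 985 TPM, JEN1 (8.39 ± 0.387), the pyruvate decarboxylase PDC5, from 9.66 ± 0.642 to 3136 ± 341 TPM, SPG4 (6.79 ± 0.177) and the decarboxylase ARO10 (6.43 ± 0.196). The largest falls were those of UTR2 (-6.35), DSE1 (-6.18), ENO2 (-6.17), SRL1 (-5.93) and OPT2 (-5.78). MUD1 rose by 1.34 ± 0.168, and by 0.31 with spike-in scaling, which ends its call. In limma 1770 genes rose and 662 fell (5168 passing at any size), a split of 1017 and 1149 after centring. Relative to a median gene at 0.43 the lists stood at 2.85 (gluconeogenesis), 2.05 (respiratory chain), 0.888 (stress), -1.31 and -1.4 (ribosomal proteins), -1.04 (ribosome biogenesis) and -1.76 (ergosterol), with limma camera adjusted p from 1.35e-19 to 0.0391 and adjusted p from 0.563 to 0.839 with an estimated correlation.

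After starvation of mud1D cells all 37 respiratory chain genes rose, and 21 of 26 gluconeogenesis genes rose and 2 fell. Among genes of the translation machinery 53 of 88 ribosome biogenesis genes fell, 71 of 89 ribosomal protein genes with an intron fell and 1 rose, and 40 of 48 without an intron fell. Of 24 ergosterol genes 15 fell and 1 rose. JEN1 (9.44 ± 0.387), MLS1 (8.25 ± 0.427), SFC1 (8.13 ± 0.596), PDC5 (8.03 ± 0.139) and ADY2 (7.82 ± 0.621) rose most. UTR2 (-6.35), ENO2 (-6.26), SRL1 (-6.03), DSE1 (-5.77) and AIM20 (-5.50) fell most. In limma 1820 genes rose and 959 fell (5221 passing at any size), a split of 1209 and 1334 after centring. Relative to a median gene at 0.358 the lists stood at 2.4 (respiratory chain), 4.0 (gluconeogenesis), -1.72 (ribosome biogenesis), -1.79 and -1.9 (ribosomal proteins) and -1.82 (ergosterol), with limma camera adjusted p from 2.33e-23 to 0.00395 and adjusted p from 0.575 to 0.756 with an estimated correlation. In all 3 mutants, the counts of these lists adjusted over the list alone were the same. With the added spike-in scaling the median gene moved to 0.259 in WT, -0.626 in hsh49::Q24P, -0.511 in nam8D and -0.427 in mud1D. The splits became 1220 up and 759 down, 527 and 2357, 528 and 2075, and 684 and 2015. The list medians named for each genotype kept their direction under it.

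**Figure D2:**
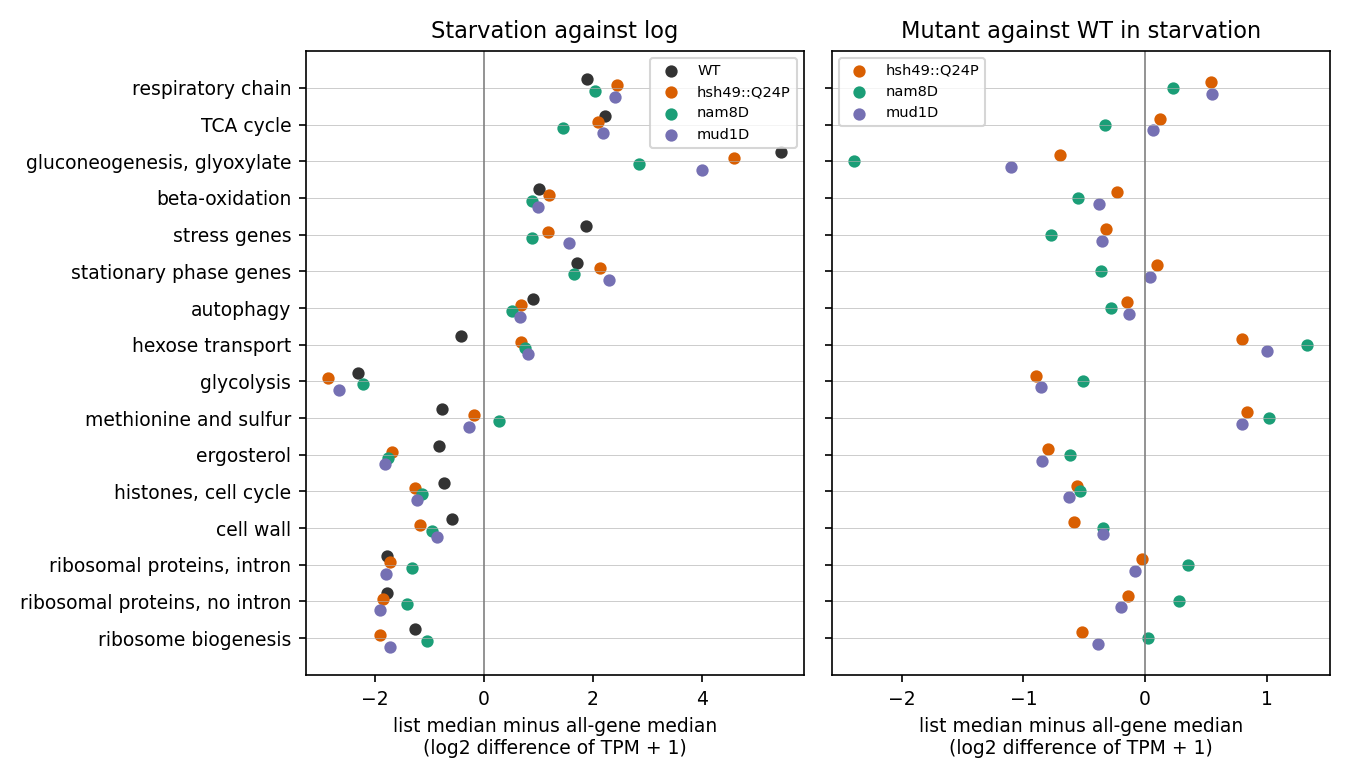
Median log2 difference of 16 gene lists minus the median of all 6449 genes, for starvation against log phase within each genotype (left) and for each mutant against WT in starvation (right); each point is a list in a genotype. On the left the respiratory chain lies between 1.89 and 2.45 and ribosome biogenesis between -1.91 and -1.04 in the 4 genotypes; on the right methionine and sulfur genes lie between 0.792 and 1.02 and ergosterol genes between -0.847 and -0.618.

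Across genes, the starvation responses of WT and a mutant correlated at r = 0.87 (hsh49::Q24P), 0.805 (nam8D) and 0.85 (mud1D), and those of the mutants with each other at 0.957, 0.979 and 0.961; these share no library, and genes are not independent replicates. WT and hsh49::Q24P shared 1290 rising genes, where independent lists would share 481.4, and 491 falling genes, where independent lists would share 81.98.

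In log phase the hsh49::Q24P mutant was close to WT, and the genes that passed the test at a lower level were mostly genes with introns. SAS5, a subunit of a histone acetyltransferase, rose from 43.9 ± 0.353 to 173.9 ± 10.6 TPM (1.96 ± 0.0688, limma adjusted p = 1.73e-13). FIT2, a cell wall protein of iron uptake, rose from 20.9 ± 12.9 to 73.5 ± 11.8 TPM (limma adjusted p = 0.0458), a call that was lost without WT replicate 2 or 3 or without any single hsh49::Q24P replicate. Apart from LEU2 and URA3, 15 genes passed at a lower level, and 11 of these have an intron, against 261 of 6445 tested genes (Fisher's exact test, two-sided, adjusted p = 2.77e-12 over 6 tests, odds ratio 67.9). Genes are not independent replicates, so this p-value may be too small. Among the genes passing at a lower level in log phase, 2 of 6 in nam8D and 3 of 21 in mud1D have an intron (Fisher's exact test, adjusted p = 0.066 and 0.102, odds ratios 11.9 and 3.98). Chosen after their values were seen, RPS22B, a ribosomal protein gene, stood at 215.1 ± 25 TPM against 409.6 ± 29.8 TPM in WT (-0.93 ± 0.141), the transcription mediator gene SRB2 at -0.60 ± 0.0763, and the actin-binding profilin PFY1 at -0.48 ± 0.0548, all under the change called.

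As lists, 173 genes with an intron outside the ribosome stood at -0.1 relative to the median gene in hsh49::Q24P log phase, with none changed, 1 member passing at a higher level and 8 at a lower level. The limma camera test gave adjusted p = 3.14e-18, and adjusted p = 0.076 with an estimated correlation. The 3 hsh49::Q24P libraries stood at -0.0854, -0.104 and -0.132 and the WT libraries at 0.00435, 0.0154 and -0.0213. Before subtracting the median gene, the list median was -0.0721, and with spike-in scaling it was 0.349, beside a median gene at 0.451. Ribosomal protein genes with an intron stood at -0.105 (adjusted p = 3.51e-10, and adjusted p = 0.666 with an estimated correlation; limma camera), and their median before subtraction turned from -0.0772 to 0.364 with spike-in scaling. That list was not particular to hsh49::Q24P: it stood at -0.093 in nam8D and -0.0724 in mud1D (limma camera adjusted p = 3.66e-06 and 0.000989; adjusted p = 0.753 and 0.839 with an estimated correlation), where spike-in scaling turned the medians before subtraction to 0.287 and 0.383. The hsh49::Q24P libraries stood at -0.0181, -0.113 and -0.187, the first of them inside the WT range of -0.0859 to 0.0455. The iron regulon stood at 0.202 with 1 of 30 genes changed and 2 adjusted over the list alone (limma camera adjusted p = 8.62e-06, and adjusted p = 0.575 with an estimated correlation). In limma 4 genes were higher and 3 lower, 30 passed at any size and 358 had an unadjusted p under 0.05; with spike-in scaling the split was 15 and 3. Outside the naming rule and chosen after their values were seen, the others were the tRNA gene IMT4 (1.59 ± 0.231), YPR170W-A (1.48 ± 0.199) and the leucine tRNA gene SUP53 (-5.25 ± 0.46); LEU2 (-5.08 ± 0.572) and URA3 (-2.32 ± 0.145) complete the 7. The URA3 call was lost with a pseudocount of 5.

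**Figure D3:**
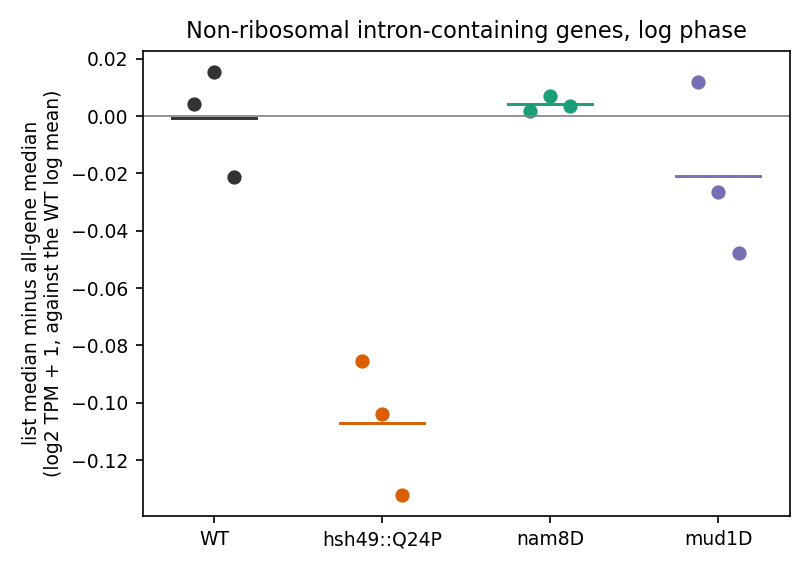
Median over 173 intron-containing genes outside the ribosome minus the median of all genes, on the log2(TPM + 1) scale, for each log-phase library against the WT mean (each WT library against the mean of the other WT libraries); points are libraries and bars are group means. The 3 hsh49::Q24P libraries lie between -0.132 and -0.0854 and the WT libraries between -0.0213 and 0.0154; before subtraction of the all-gene median, spike-in scaling turns the hsh49::Q24P list median to 0.349.

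The nam8D mutant in log phase differed from WT in 8 genes, 4 higher and 4 lower. COS2, a member of a gene family of near-identical subtelomeric copies, so that the copy is uncertain, rose from 10.8 ± 1.81 to 42.5 ± 6.3 TPM (1.89 ± 0.2, limma adjusted p = 1.15e-05). NAM8 (-4.66), LEU2 (-8.84) and SUP53 (-7.08) were lower, and URA3 was listed at 0. Chosen after their values were seen, the other rises were YER188W (1.41 ± 0.0929), YER187W (1.01 ± 0.113) and YLR154W-F, which lies in the ribosomal DNA (1.43 ± 0.255). None of the stress, trehalose and glycogen, hexose transport or ribosome biogenesis genes changed in limma, but as lists they stood at 0.314, 0.368, 0.439 and -0.162 relative to the median gene. Their limma camera adjusted p were 2.55e-09, 1.68e-07, 5.54e-06 and 3.79e-11, and adjusted p = 0.575, 0.607, 0.509 and 0.633 with an estimated correlation. Before subtraction the ribosome biogenesis median was -0.163 and turned to 0.213 with spike-in scaling. In limma 19 genes passed at any size and 608 had an unadjusted p under 0.05; with spike-in scaling the median gene stood at 0.357 and the split was 9 and 4.

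The mud1D mutant in log phase differed from WT in 20 genes, 7 higher and 13 lower, a balance that turned to 44 higher and 9 lower with spike-in scaling, where the median gene stood at 0.438. INO1, the enzyme of inositol synthesis, fell from 128.3 ± 42 to 40.7 ± 5.02 TPM (-1.58 ± 0.223, limma adjusted p = 0.000455), and COS8, of the same subtelomeric family, from 48.1 ± 4.96 to 12.8 ± 1.85 TPM (-1.83 ± 0.108). The zinc transporter ZRT1 (-1.21 ± 0.225) lost its call without WT replicate 2 or 3 or mud1D replicate 1, and BTN2 (-1.36 ± 0.319, limma adjusted p = 0.0438) lost it without any of 5 single libraries. MUD1 (-3.40), LEU2 (-10.25) and SUP53 (-8.03) were lower, and URA3 was listed at 0. Chosen after their values were seen, several features of the ribosomal DNA were higher: RDN5-1 (3.78 ± 0.586), YLR154W-F (2.63 ± 0.255), YLR154C-H (1.89 ± 0.302) and YLR154W-E (1.34 ± 0.208). These overlap other transcripts and repeats, and the strand of counting is not stated. Of 28 methionine and sulfur genes and 30 iron regulon genes none changed in limma over all genes, and 2 iron genes did so adjusted over the list alone. The lists stood at -0.189 and 0.195 relative to the median gene (limma camera adjusted p = 2.93e-08 and 2.23e-07, and adjusted p = 0.575 for both with an estimated correlation). The methionine median before subtraction was -0.158 and turned to 0.266 with spike-in scaling. In limma 59 genes passed at any size and 534 had an unadjusted p under 0.05.

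In starvation all 3 mutants stood far from WT, and several hexose transport genes were higher. Of 20 glycolysis genes 2, 3 and 3 rose and 10, 5 and 10 fell in hsh49::Q24P, nam8D and mud1D. The pyruvate decarboxylase gene PDC5 was at 102.3 ± 10.8 TPM in WT and at 1851 ± 467, 3136 ± 341 and 2333 ± 237 TPM in hsh49::Q24P, nam8D and mud1D; the split of reads between PDC5 and its near-identical copy PDC1 is uncertain. The glucose transporter HXT3 was at 233.4 ± 18.6 TPM in WT and at 2593 ± 977, 4451 ± 331 and 2412 ± 907 TPM in the mutants. HXT4 was at 103.2 ± 16.2 TPM in WT against 1167 ± 778, 1799 ± 475 and 1587 ± 780 TPM, with the same limit for transporter copies. The glucose-induced repressor MIG2 was higher by 2.87 ± 0.256, 3.62 ± 0.256 and 2.75 ± 0.256, REE1 by 2.69 ± 0.0836 in hsh49::Q24P and 2.85 ± 0.0836 in mud1D, and PFK27, a kinase that makes an activator of glycolysis, by 3.26 ± 0.291 in nam8D and 3.10 ± 0.291 in mud1D. Of 12 hexose transport genes 5, 7 and 6 rose and 2, 2 and 1 fell. Among the largest falls against WT, GRE1 was at 773 ± 149 TPM in WT and 17.3 ± 7.59, 7.91 ± 0.947 and 18.4 ± 9.23 TPM in the mutants. DPA10 was at 7545 ± 840 TPM in WT against 143.4 ± 56, 47.6 ± 2.71 and 121 ± 72.5 TPM.

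Some of the methionine and sulfur genes were higher and some of the ergosterol genes lower in each starved mutant. Of 28 methionine and sulfur genes 11, 14 and 11 rose and 0, 1 and 0 fell. MET2, the first step from homoserine to methionine, rose from 67.2 ± 3.91 to 326.1 ± 34.3 TPM in hsh49::Q24P, and the sulfate carrier SUL2 rose by 2.69 ± 0.1 in nam8D and 2.27 ± 0.1 in mud1D. LEU1, which acts before LEU2 in leucine synthesis, rose by 1.62 ± 0.141, 2.18 ± 0.141 and 1.62 ± 0.141, beside the LEU2 difference itself (-11.18, -9.74 and -9.67). Of 24 ergosterol genes 11, 8 and 11 fell. ERG13, which makes the precursor of mevalonate, fell from 142.9 ± 11.9 to 19.6 ± 3.32, 24.9 ± 3.99 and 18.8 ± 1.66 TPM. Of 35 histone and cell-cycle genes 13, 13 and 12 fell, with the cyclin PCL1 at -3.62 ± 0.238, -3.28 ± 0.238 and -3.16 ± 0.238. Of 31 cell wall genes 12, 10 and 10 fell and 1 rose in each mutant, with the mannoprotein CWP1 at -3.58 ± 0.269, -4.56 ± 0.269 and -3.28 ± 0.269. Of 20 mating-type genes 8, 6 and 8 fell, among them the agglutinin AGA2 (-2.10 ± 0.145, -1.97 ± 0.145 and -2.48 ± 0.145). In the respiratory chain 2 of 37 genes rose and 1 fell in each mutant: CYC7, a minor cytochrome c, rose by 2.58 ± 0.216, 2.16 ± 0.216 and 2.73 ± 0.216, and NDE2 fell (-1.05, -2.43 and -1.67). The NDE2 call in hsh49::Q24P was lost without hsh49::Q24P replicate 2 (-0.38), WT replicate 1 (-0.99) or WT replicate 2 (-0.95), and with median centring (-0.93), trimmed mean scaling (-0.94) and library weights (-0.54).

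**Figure D4:**
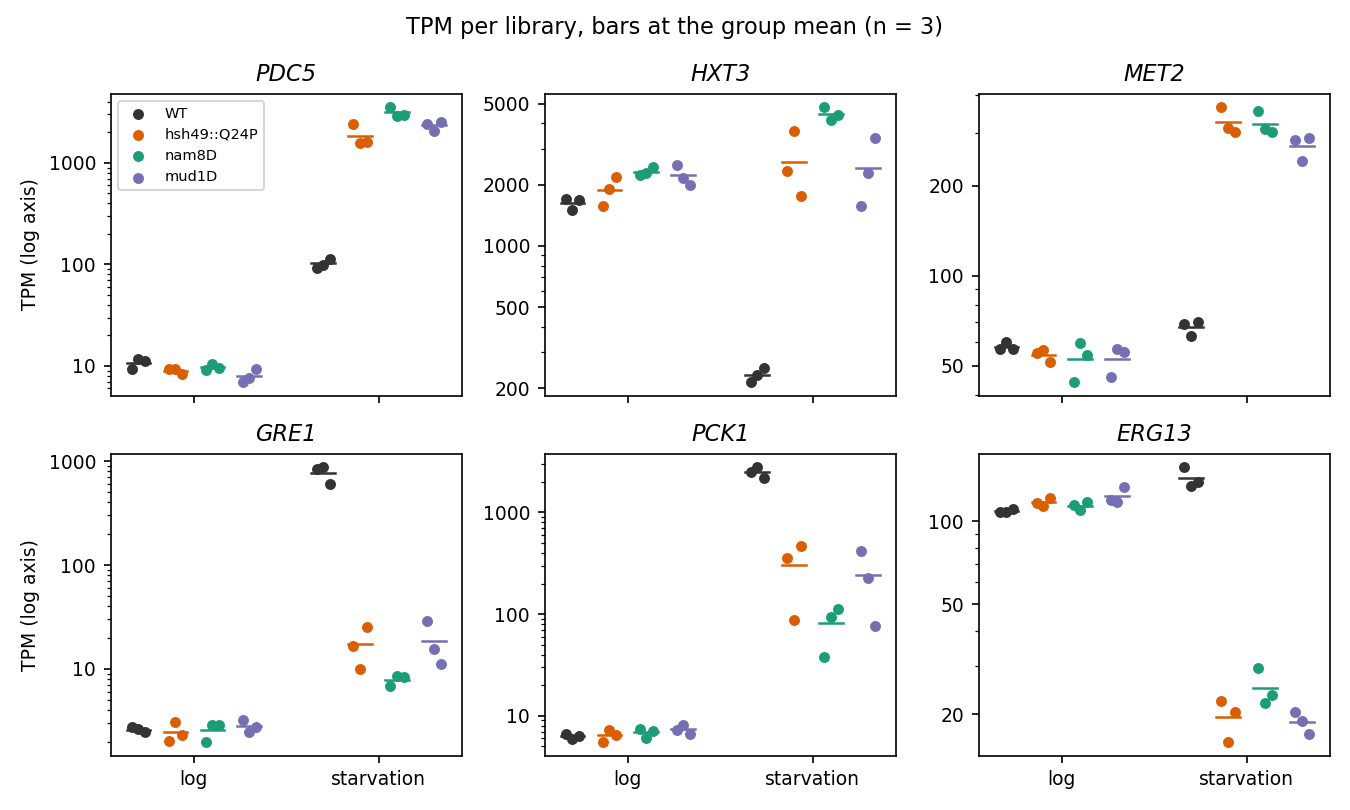
TPM of 6 genes in each of the 24 libraries, on a log axis; points are libraries, bars are group means (n = 3) and colours are genotypes. In starvation PDC5, HXT3 and MET2 are higher in the mutants than in WT (HXT3 at 233.4 TPM in WT and at 2593, 4451 and 2412 TPM in hsh49::Q24P, nam8D and mud1D), and GRE1, PCK1 and ERG13 are lower.

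Most gluconeogenesis genes and some stress genes were lower in starved nam8D, and the lists were not tested between mutants. Of 26 gluconeogenesis genes 20 fell in nam8D and none rose, while 8 fell and 3 rose in hsh49::Q24P and 13 fell and 3 rose in mud1D. The alcohol dehydrogenase ADH2 stood at 941.3 ± 156 TPM in WT, 16.8 ± 6.22 TPM in nam8D and 87.1 ± 69.9 TPM in mud1D, and the gluconeogenic carboxykinase PCK1 at 2495 ± 286 TPM in WT and 303.3 ± 195 TPM in hsh49::Q24P. Single libraries overlapped: PCK1 stood at 88.11 TPM in hsh49::Q24P replicate 2 and at 77.14 TPM in mud1D replicate 3, inside the range of the nam8D libraries, 37.97 to 111.5 TPM. Stress genes fell in 15 of 37 cases and rose in 2 in nam8D, fell in 10 and rose in 3 in hsh49::Q24P, and fell in 10 and rose in 2 in mud1D. In nam8D the desiccation gene SIP18 fell by 5.31 on the log2 scale. Ribosome biogenesis genes fell in 19 of 88 cases in hsh49::Q24P and 18 in mud1D, but in 2 in nam8D, where 2 of 89 intron-containing ribosomal protein genes rose and 47 passed at a higher level.

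The limma counts against WT in starvation were 254 higher and 478 lower in hsh49::Q24P (3887 passing at any size), 283 and 507 in nam8D (3870) and 295 and 572 in mud1D (4164). The counts at any size may be too high, because in simulated starvation data more unchanged genes passed than the threshold sets. Centred on the library medians, the hsh49::Q24P and mud1D splits became 345 and 379, and 376 and 453. Spike-in scaling moved the median gene to -0.486, -0.428 and -0.297 and the splits to 92 and 1148, 131 and 1080, and 160 and 857. Relative to the median gene, methionine and sulfur genes stood at 0.836, 1.02 and 0.792 (limma camera adjusted p = 2.04e-05, 4.35e-08 and 0.000122; adjusted p = 0.614, 0.575 and 0.63 with an estimated correlation). Ergosterol genes stood at -0.796, -0.618 and -0.847 (adjusted p = 0.000124, 0.00159 and 0.000305 in limma camera; adjusted p = 0.575, 0.592 and 0.575 with an estimated correlation). Histone and cell-cycle genes stood at -0.562, -0.534 and -0.629, cell wall genes at -0.584, -0.349 and -0.349, mating-type genes at -0.628, -0.76 and -0.695, and hexose transport genes at 0.798, 1.33 and 1.0, with limma camera adjusted p from 4.51e-06 to 0.0127 and adjusted p from 0.575 to 0.614 with an estimated correlation. The respiratory chain stood at 0.541, 0.226 and 0.547 (limma camera adjusted p = 4.59e-08, 0.00732 and 5.27e-07; adjusted p = 0.614, 0.78 and 0.623 with an estimated correlation), and in nam8D its median before subtraction turned from 0.194 to -0.239 with spike-in scaling.

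Glycolysis genes stood at -0.898, -0.509 and -0.853 relative to the median gene (limma camera adjusted p = 0.00236, 0.114 and 0.00747; adjusted p = 0.641, 0.811 and 0.671 with an estimated correlation), so the test passed in hsh49::Q24P and mud1D with the preset correlation. Gluconeogenesis genes stood at -2.39 in nam8D (limma camera adjusted p = 0.000101, and adjusted p = 0.666 with an estimated correlation), and at -0.699 and -1.1 in hsh49::Q24P and mud1D, where the test did not pass (adjusted p = 0.375 and 0.108 in limma camera). Stress genes stood at -0.77 in nam8D (limma camera adjusted p = 0.000664, and adjusted p = 0.666 with an estimated correlation). Ribosome biogenesis stood at -0.521 and -0.389 in hsh49::Q24P and mud1D (limma camera adjusted p = 2.54e-07 and 6.55e-05; adjusted p = 0.684 and 0.769 with an estimated correlation) and at 0.0203 in nam8D, where the median before subtraction was -0.0113 and the test did not pass (limma camera adjusted p = 0.803). Intron-containing ribosomal protein genes stood at 0.353 in nam8D (limma camera adjusted p = 2.04e-05, and adjusted p = 0.773 with an estimated correlation), and their median before subtraction turned from 0.321 to -0.112 with spike-in scaling. Adjusted over the list alone, the counts of all these lists were the same. MUD1 was 0.41 and 0.48 higher than in WT in starved hsh49::Q24P and nam8D (limma adjusted p = 0.0421 and 0.018), and HSH49 0.27 higher in hsh49::Q24P (limma adjusted p = 0.012), all under the change called.

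The starvation response itself differed between each mutant and WT, by the interaction term of the model. The response of PDC5 was larger by 4.37 ± 0.197 in hsh49::Q24P, 5.05 ± 0.197 in nam8D and 4.89 ± 0.197 in mud1D, and those of HXT3 and HXT4 were larger by 3.21, 3.75 and 2.86 and by 2.86, 3.26 and 3.08 on the log2 scale. The response of DPA10 was smaller, at -6.16, -7.64 and -6.83, as was that of GRE1, at -5.41, -6.41 and -5.48. Responses of 2, 3 and 2 of 20 glycolysis genes were higher and of 10, 7 and 9 lower. Responses of 13, 16 and 13 of 28 methionine and sulfur genes were higher and of 0, 1 and 0 lower. Those of 12, 8 and 12 of 24 ergosterol genes and of 13, 13 and 12 of 31 cell wall genes were lower, with 1 cell wall gene higher in nam8D. In nam8D, responses were also lower for 19 of 26 gluconeogenesis genes, 18 of 37 stress genes (2 higher), 12 of 20 trehalose and glycogen genes and 7 of 22 TCA cycle genes. In limma 216 genes responded more and 508 less in hsh49::Q24P (2966 passing at any size), 272 and 565 in nam8D (3057), and 257 and 617 in mud1D (3204). Centred on the medians, the hsh49::Q24P and mud1D splits became 314 and 386, and 362 and 467, and with spike-in scaling the 3 splits became 50 and 2832, 79 and 2219, and 73 and 2063.

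Relative to the median gene, the methionine and sulfur responses stood at 1.05, 1.35 and 0.987 (limma camera adjusted p = 2.83e-07, 1.81e-10 and 4.8e-07; adjusted p = 0.575, 0.575 and 0.592 with an estimated correlation). The glycolysis responses stood at -0.92, -0.697 and -0.775 (limma camera adjusted p = 0.00038, 0.0117 and 0.0063; adjusted p = 0.614, 0.684 and 0.666 with an estimated correlation). The ergosterol responses stood at -0.85, -0.634 and -0.87, and the cell wall responses at -0.678, -0.57 and -0.389 (limma camera adjusted p from 1.27e-05 to 0.00464, and adjusted p from 0.575 to 0.621 with an estimated correlation). In nam8D the gluconeogenesis, stress, trehalose and glycogen, and TCA cycle responses stood at -2.57, -0.857, -1.13 and -0.462 (limma camera adjusted p = 1.28e-05, 1.38e-06, 0.000557 and 0.000155; adjusted p = 0.641, 0.614, 0.671 and 0.575 with an estimated correlation). The counts of these lists adjusted over the list alone were the same. LEU2 was among the largest differences of response in hsh49::Q24P, at -6.10 ± 0.81, and that value rests on its log-phase RNA in that mutant.

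The differences of the starved mutants from WT were shared. All 3 mutants also lacked the LEU2 and URA3 RNA of WT in starvation, so a strain difference cannot be told apart from the mutations as the source of shared genes. Of the genes changed against WT, 165 were higher and 320 lower in all 3 mutants. The balance rests on the scaling, with 68 higher and 677 lower under spike-in scaling, 222 and 260 under quantile normalization and 199 and 256 under median centring. Between pairs of mutants 181 to 215 higher genes were shared, where independent lists would share 11.1 to 12.9, and 337 to 435 lower genes, where independent lists would share 37.6 to 45. The differences correlated across genes at r = 0.886, 0.955 and 0.894. Simulated mutants without change, set against a shared simulated WT, gave r = 0.489, so part of the correlation may come from the shared controls. The simulation used the spread of the model, which pools both growth states, and genes are not independent replicates. The covariances were 0.481, 0.501 and 0.514, against 0.0142 in the simulation. In log phase the pairs gave r = 0.638, 0.594 and 0.647 with covariances of 0.0309, 0.0304 and 0.0436, no gene was higher in all 3 mutants by the limma call, and the 3 lower in all were LEU2, URA3 and SUP53.

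In starvation the mutants differed from each other in fewer genes than from WT. Apart from NAM8 and MUD1, the genes named in these direct comparisons were chosen after their values were seen. In starvation hsh49::Q24P and nam8D differed in 77 genes, 65 higher and 12 lower in hsh49::Q24P. SFC1, MLS1 and ADH2 were 3.21, 2.72 and 2.60 higher in hsh49::Q24P, and the nucleolar NSR1 and the ribosomal protein gene RPS22A were lower (-1.66 and -1.12). Between nam8D and mud1D 72 genes differed, 25 higher and 47 lower in nam8D, again with SFC1 and MLS1 lower (-2.63 and -2.37) and NSR1 and RPS22A higher (1.18 and 1.28). Starved hsh49::Q24P and mud1D differed in 17 genes, 14 higher and 3 lower in hsh49::Q24P, among them SAS5 (1.55) and COS8 (1.48) higher and RDN5-1 (-2.93) and YLR154W-F (-2.74) lower. In log phase limma called 8, 18 and 12 genes between hsh49::Q24P and nam8D, hsh49::Q24P and mud1D, and nam8D and mud1D; SAS5 was higher in hsh49::Q24P than in either deletion (1.96 and 1.88). Fitted with only the groups compared, the starvation counts were 10 between hsh49::Q24P and nam8D, 14 between nam8D and mud1D and 6 between hsh49::Q24P and mud1D. They also rest on single libraries: without hsh49::Q24P replicate 2 the count against nam8D was 181 and that against mud1D was 52, without nam8D replicate 1 the count against hsh49::Q24P was 42 and that against mud1D was 36, and without mud1D replicate 3 the count between the deletions was 142.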

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

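In this part the comparisons of hsh49::Q24P with nam8D, the tests of scaling, the test of an earlier point for nam8D alone, the tests of strain markers and marker RNA in the hsh49::Q24P log libraries, and the fits with spike-in scaling were chosen after the results were seen.

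Intron-containing genes outside the ribosome stood slightly lower in hsh49::Q24P than in WT in log phase. A trend with expression level is argued against: none of 10000 expression-matched lists of intronless genes had a median as low, so the percentile was 0 (list median -0.0721, matched lists 0.0039 to 0.0634). A single library does not set it, since 3 of 3 hsh49::Q24P libraries lay below the lowest WT library, and neither do the WT libraries, since the difference from nam8D was -0.111. Reduced splicing or stability of these transcripts in the U2 snRNP mutant is a possible explanation, offered as a hypothesis found and examined in the same libraries. Gene-level TPM do not separate spliced from unspliced RNA, and the estimated-correlation test of this list against WT did not pass (limma camera adjusted p = 0.076).

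The starved mutants differed from WT in many of the same genes. An earlier point of the WT response as the whole cause in all 3 mutants is argued against only for genes that do not turn between log phase and 48 h. Of the genes with a changed response that also changed in starved WT, 57.4% in hsh49::Q24P and 61.1% in mud1D moved opposite to the WT response. Of those that rose in WT, 74.2% and 75.2% moved opposite, but 99 of 138 and 93 of 133 of those that fell in WT fell further. WT was not sampled in between, so genes that dip before 48 h could give the same, and an earlier point is not excluded. The WT libraries also enter both values compared, which favours opposite signs. For nam8D alone an earlier point cannot be told apart either, because 75.5% moved opposite. By the bounds set for all 3 mutants that is too many to exclude an earlier point and too few to be what it needs. Of those that rose in WT 83.5% moved opposite, and 57 of 111 that fell in WT fell further. At least 97.6% of the shared higher and 99.7% of the shared lower genes passed the adjusted threshold in the same direction in each mutant under 4 other scalings. These genes had been picked at a difference of at least 1 in the same data. The other scalings shifted their medians by less, so passing was largely set in advance. The share passing therefore does not by itself exclude scaling as the whole cause. A single factor per library moves all genes the same way, but the shared genes stood on both sides of WT. The 320 lower genes had medians of -1.49 ± 0.964, -1.64 ± 1.08 and -1.66 ± 0.929, and -1.88, -2.01 and -1.84 with spike-in scaling. All 320 lower and all 165 higher genes kept their direction under each scaling. This argues against scaling as the whole cause for these genes, but not for their balance. With spike-in scaling the higher genes went from medians of 1.43 ± 0.541, 1.63 ± 0.622 and 1.51 ± 0.553 to 0.995 ± 0.537, 1.21 ± 0.618 and 1.29 ± 0.55 (SD over genes). Only 41.2% of them stayed called in all 3 because that shift takes many under a difference of 1. A strain difference cannot be told apart either, because 3 of 3 mutants lacked most LEU2 RNA in starvation, and a shared effect of early splicing factors was not tested.

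The hsh49::Q24P log libraries held LEU2 and URA3 RNA at a few percent of WT, at 8.97% and 9.25% in replicate 1. WT RNA or cells in that library may explain it: the percentage for URA3 divided by that for LEU2 was 1.03, near the 1 that a mixture gives, and 0.668 in replicate 2. These ratios rest on URA3 at 0.4585 and 0.075 TPM, at unknown depth. SUP53, whose RNA was more abundant than that of URA3, stood at 7.96% of WT in replicate 1. In replicates 2 and 3 it stood at 1.03% and 1.16%, beside LEU2 at 2.26% and 1.21%, so the markers were less alike in replicate 2. An even exchange of reads between all libraries is argued against, since the highest LEU2 in nam8D and mud1D log libraries was only 0.0662 of that in hsh49::Q24P replicate 1. A mixed culture and a mixed RNA sample were not separated. A fit with replicate 3 as the lone hsh49::Q24P log library gave 704 genes for the response and 5 against WT in log phase, but that library still held LEU2 at 1.21% of WT and was assumed to vary like the other groups, so it does not show these counts to be free of such RNA.

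The responses to starvation differed between each mutant and WT by the interaction term, which is why the following values are given. In hsh49::Q24P 724 genes differed, and the named genes were PDC5 (4.37), HXT3 (3.21), HXT4 (2.86), MIG2 (2.77), REE1 (2.55), DPA10 (-6.16), LEU2 (-6.10), GRE1 (-5.41), GND2 (-4.08) and TKL2 (-3.84). In nam8D 837 genes differed, with PDC5 (5.05), HXT3 (3.75), MIG2 (3.32), HXT4 (3.26), PFK27 (3.24), DPA10 (-7.64), GRE1 (-6.41), ADH2 (-5.85), SIP18 (-5.28) and PCK1 (-5.16). In mud1D 874 genes differed, with PDC5 (4.89), HXT4 (3.08), HXT3 (2.86), PFK27 (2.85), REE1 (2.60), DPA10 (-6.83), GRE1 (-5.48), AQY1 (-4.49), GND2 (-4.30) and PHO89 (-4.01).

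Of 100 splits of the samples, 9, 1 and 3 gave at least as many genes as the real responses of hsh49::Q24P, nam8D and mud1D (724, 837 and 874), with 778, 834 and 894 as the highest other. Every split that reached the real count kept the real grouping of the starvation libraries, and splits that regrouped those gave at most 0, 1 and 2 genes by the limma call. Exchanging log libraries hardly moved the count, so these shares do not separate a difference of response from a difference in starvation. Chance is not excluded for hsh49::Q24P, and the lower shares of the deletions are no firmer for that reason. The other comparisons have 10 splits, too few for a share under 0.05. Starvation against log phase gave 2272, 2746, 2432 and 2779 genes in WT, hsh49::Q24P, nam8D and mud1D, and the highest other split gave 0. Against WT in log phase the counts were 7, 8 and 20 with 0 as the highest other, and in starvation 732, 790 and 867 with 1, 0 and 0. Between mutants in log phase they were 8, 18 and 12 with 0, 1 and 0, and in starvation 77, 17 and 72 with 8, 156 and 1, in the order hsh49::Q24P against nam8D, hsh49::Q24P against mud1D and nam8D against mud1D. For hsh49::Q24P against mud1D in starvation 2 of the 10 splits gave at least 17 genes. The split with 156 genes sets hsh49::Q24P replicates 1 and 3 with mud1D replicate 1 against the others, and points to a structure of the samples beside genotype.

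The mean share of TPM held by some features outside the tests was above that in WT. Ribosomal DNA spacers held 0.572% of TPM in mud1D log phase and 0.4996% in mud1D starvation, against 0.0854% and 0.0746% in WT. Spike-in RNAs held 1.94%, 1.94% and 1.66% of TPM in hsh49::Q24P, nam8D and mud1D starvation, against 1.43% in WT starvation. In log phase the shares were 0.878%, 0.902% and 0.893% in hsh49::Q24P, nam8D and mud1D against 1.16% in WT. These spike-in shares overlapped. In starvation hsh49::Q24P replicate 1 (1.46%), nam8D replicate 3 (1.48%) and mud1D replicate 3 (1.34%) lay inside the WT range of 1.31% to 1.63%. In log phase nam8D replicate 3 (1.02%) lay inside the WT range of 1.01% to 1.26%. Origins held 0.182% of TPM in mud1D log phase, against 0.0857% in WT, and 0.289% in mud1D starvation, against 0.242% in WT.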

How the results depend on the processing

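Spike-in scaling, a test of all lines, fits within a growth state and the fit without both hsh49::Q24P log libraries richest in LEU2 RNA were chosen after seeing the data. All 19 counts stayed within 1.5 times under pseudocount 0.1, no filter, no trend, mRNA only, median centring, quantile and trimmed mean scaling and a replicate block. With a pseudocount of 5 the counts against WT were 3, 5 and 11 in log phase for hsh49::Q24P, nam8D and mud1D and 472 in hsh49::Q24P starvation, the mud1D response 571, hsh49::Q24P against mud1D 11 in log phase and 7 in starvation, hsh49::Q24P against nam8D 4 in log phase, and nam8D against mud1D 7 in log phase. With spike-in scaling they were 18, 13 and 53 against WT in log phase, 1240 and 1211 in hsh49::Q24P and nam8D starvation, 2882, 2298 and 2136 for the responses, and 10 for hsh49::Q24P against mud1D in starvation. With all lines tested, nam8D and mud1D log phase gave 15 and 34, hsh49::Q24P against mud1D 34 in log phase and 33 in starvation, hsh49::Q24P against nam8D 14 and nam8D against mud1D 22 in log phase. Library weights gave 13 and 32 for nam8D and mud1D in log phase, 29 for nam8D against mud1D in log phase, and 155 and 85 for hsh49::Q24P against nam8D and mud1D in starvation. With only the groups compared, mud1D log phase gave 13, hsh49::Q24P against nam8D 5 in log phase and 10 in starvation, hsh49::Q24P against mud1D 6 and nam8D against mud1D 14 in starvation. Fits within starvation gave 46, 11 and 42 for hsh49::Q24P against nam8D, hsh49::Q24P against mud1D and nam8D against mud1D; the stricter filter gave 9 for the second, and without both LEU2-rich libraries, which leaves 1 hsh49::Q24P log library assumed to vary like the other groups, hsh49::Q24P against nam8D in log phase gave 4. Leaving out 1 library, starvation counts ranged over 2221 to 2290 (WT), 2694 to 2852 (hsh49::Q24P), 2404 to 2563 (nam8D) and 2725 to 2899 (mud1D). Counts against WT ranged over 6 to 9, 6 to 10 and 17 to 22 in log phase and 635 to 839, 773 to 835 and 787 to 980 in starvation, and responses over 650 to 841, 795 to 879 and 788 to 987. Between mutants they ranged over 6 to 8, 15 to 18 and 8 to 11 in log phase. In starvation they ranged over 42 (without nam8D replicate 1) to 181 (without hsh49::Q24P replicate 2; 46 without its replicate 3) for hsh49::Q24P against nam8D, 10 (without hsh49::Q24P replicate 1) to 52 (without its replicate 2) against mud1D, and 36 (without nam8D replicate 1) to 142 (without mud1D replicate 3; 45 without its replicate 1) for nam8D against mud1D. MUD1 in hsh49::Q24P starvation turned to -0.02453 with spike-in scaling. For the proteasome list it was the direction of the camera test that reversed. Relative to the median gene the list stood at -0.122 in WT starvation in the main fit. The direction reversed there with median centring, quantile and trimmed mean scaling, at -0.122, -0.0311 and -0.17. In hsh49::Q24P starvation, at -0.0022 in the main fit, it reversed with quantile and spike-in scaling, at -0.0666 and -0.0997. In nam8D log phase it reversed with quantile scaling, at -0.0055. The stress list in hsh49::Q24P log phase ranged from -0.00922 without hsh49::Q24P replicate 2 to 0.17 without its replicate 1. Of the planned repeats for named genes 16687 had the same status as in the main fit, called or not, 252 lost a call and 69 gained one. The named genes include markers entered in every comparison whether called or not, so the first number is not a number of kept calls. For lists called in the main fit 4213 repeats kept the call and 191 lost it. These repeats all used the preset correlation, and none of the 230 list calls passed with an estimated correlation. Under at least 1 other scaling, 55 of the 230 list medians changed sign before subtraction of the median gene, and 5 did so after it. Samples share only a replicate number. In the 10 planned pairs of groups, same-numbered libraries correlated at -0.312 to 0.279, and in none did all 3 pass 0.1. In the 6 pairs of mutants they correlated at -0.671 to 0.463, and hsh49::Q24P with nam8D in starvation gave 0.144, 0.141 and 0.201, with 6 of 6 libraries closest to their own number, as a hint of pairing; with the block that count was 75 against 77. Beyond fewer genes or libraries in a fit, the cause was not tested. Depth is unknown, so what it limits cannot be stated.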

Other observations

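The tests of Leu3 targets and the genes MND1, SPO74, MUM3 and LDS2 were chosen after the results were seen. Leu3 activates genes of leucine synthesis when an intermediate made before the step of LEU2 builds up, and its targets other than LEU2 were examined because LEU1 was higher in the starved mutants. In starvation the 10 targets stood at 1.02, 1.64 and 0.968 relative to the median gene in hsh49::Q24P, nam8D and mud1D, with 5, 8 and 4 of them higher (limma camera adjusted p = 0.000111, 3.14e-05 and 0.00106; adjusted p = 0.178, 0.178 and 0.214 with an estimated correlation). LEU1, which prompted the test, is one of the 10; without it the other 9 stood at 0.874, 1.51 and 0.856, with 4, 7 and 3 of them higher (limma camera adjusted p = 0.00057, 0.000205 and 0.00432; adjusted p = 0.214, 0.214 and 0.264 with an estimated correlation). A missing LEU2 that raises these targets in every condition is argued against, since in log phase the 10 stood at 0.0173 at most and the 9 at 0.0184 at most. An effect of the missing LEU2 that appears only in starvation may explain the difference and was not tested.

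Iron regulon genes rose in 5, 4 and 4 of 30 cases and fell in 0, 2 and 1 in starved hsh49::Q24P, nam8D and mud1D against WT. The list stood at 0.432, 0.262 and 0.415 relative to the median gene (limma camera adjusted p = 0.00226, 0.0174 and 0.00369; adjusted p = 0.641, 0.711 and 0.655 with an estimated correlation), and with spike-in scaling its median before subtraction turned to -0.0728 in hsh49::Q24P and -0.198 in nam8D. Of 35 listed meiosis and sporulation genes 7, 7 and 6 fell and none rose by the limma call, with the list at -0.297, -0.402 and -0.315 relative to the median gene (limma camera adjusted p = 0.0288, 0.0105 and 0.0366; adjusted p = 0.641, 0.614 and 0.645 with an estimated correlation). Outside the list the meiosis and sporulation genes MND1, SPO74, MUM3 and LDS2 were higher in all 3 mutants, MND1 by 1.26, 1.52 and 1.58. The meiotic activator IME1 fell from 306.7 ± 26.7 to 54.6 ± 30.4, 48.6 ± 4.89 and 39.7 ± 13.9 TPM.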
